A study of Mus musculus with 3 samples.

How the data were processed

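Live cells positive for tdTomato and MHC class II were sorted from digested tissue of 2-week-old RORγt-lineage reporter mice and processed with the 10x Chromium version 3 chemistry for 3′ ends, per the labels' protocols. The deposited values are whole-number UMI counts per gene and barcode, with no normalization by the authors visible in them. Cell Ranger 8.0.1, Scanpy 1.10.2 and the build mm10 are named in the submitters' processing notes, without their roles or order. Steps between reads and counts beyond these are not given in the sources used here. The 3 libraries had 1 shared list of 33698 features, including the reporters tdTomato and egfp, and 1737 of these features were absent by gene ID from GENCODE vM21. The build was therefore taken from the notes, and coordinates come from vM21. Groups follow the titles, since titles and tissue fields of both lymph node libraries conflict and values were not used to settle this. The counts of 1 library, that titled as mesenteric, were analysed.

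Barcodes were kept with at least 500 genes and under 10% mitochondrial UMIs: 227 of 13482 fell under the gene minimum, 467 reached the mitochondrial limit, and 12892 passed. Scrublet, as in scanpy 1.11.5, with an expected rate of 0.8% per 1000 cells, called 584 doublets (4.53%), which were removed. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were taken outside mitochondrial genes, immunoglobulin and T cell receptor segments, reporters and the functional lists. Principal components (30) were computed exactly, 15 exact nearest neighbours were joined by shared neighbours, and Leiden clustering (leidenalg 0.10.2, resolution 1, seed 1) gave 22 clusters. Sub-clusters used resolution 0.5. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

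The marker lists of 20 cell types, the 17 functional lists with 170 genes in the files, the comparisons, the first set of alternative settings and the rule for named genes were fixed before the data were examined. The rule that scores clusters with the markers was not. It was revised while looking at the names it gave, and version 6 is used. Versions 1 to 3 scored clusters by marker level relative to the highest cluster, with changes to undetected and shared markers. Version 4 used the mean log2 fold over all other cells, with 10 CPM added. Version 5 required leading genes to be present in 10% of the cluster's cells, and version 6 left a cluster unnamed on a tie with another class. Cluster 13, with 222 of the 603 RORγt DC-like cells, was unnamed under versions 1 to 3 and named from version 4 on. Cluster 3, with 1282 cells, was unnamed under versions 1 to 4, and clusters 15 and 16 also changed names between versions. The RORγt DC-like class had 381 cells under versions 1 to 3. All 6 versions were recomputed.

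In the version used, a cluster takes the class with the highest score among classes with at least 3 markers present in 10% of its cells. It stays unnamed if another class has as many markers among its 10 leading genes of at least 50 CPM, if 3 of these are cell cycle genes, or if its median UMI count is under 3014 (the library's median divided by 3) with no own marker among them. Cluster 9, at 3057 UMIs, lies just above that limit.

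UMIs were summed per class and expressed as counts per 1000000 UMIs (CPM). Intervals are exact Poisson for sums, exact binomial for shares and exact conditional binomial for ratios, at 95%, and cover counting error only. The intervals of 3 tests among the additional observations, those of gene span, of correlation and of the UMIs held by the top T cell-like cells, are instead percentile bootstraps with 1000 draws of genes or cells. A count of 0 was set to 3 counts over the class for ratios. Genes of a list were described with at least 50 UMIs in both classes together, and called higher or lower at 2-fold with an interval excluding 0. List medians were ranked among 10000 random lists matched on mean expression. Named genes were, per list, up to 2 with the highest and 2 with the lowest ratio of at least 2-fold, always Itgb8, Aire, Ccr7, H2-Ab1 and Zbtb46, and the 5 highest and 5 lowest ratios among genes with at least 100 UMIs used in no list, clustering or naming. From this set, the text gives a part and summarises the rest. Some results that the design named are not reported here. The contrast of sub-cluster 3 with sub-cluster 2 was chosen after their levels were seen and uses the same rule. Under an alternative, a sub-cluster counted as matched when it shared at least 0.5 of the joint cells, a requirement also set after seeing the data. Of the list symbols 5 were matched through gene IDs and 1 was not matched.

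The ratio step was tested on simulated counts, for counting error only. Coverage near 95% follows where counts vary as the intervals assume. The ratio test therefore does not tell how the calls hold with variation between cells, animals or clusters in the real classes. In the simulated comparison with ILC3-like cells (14772 genes), 96.97% of 99 changes of 4-fold and 100% of 100 changes of 8-fold were called, 77 unchanged genes were called, and 95.5% of intervals held the true ratio. With mature DC-like cells (10423 genes), 100% of 87 changes of 4-fold and of 77 of 8-fold were called, with 59 false calls and 96.01% of intervals holding the true ratio. For the sub-clusters (8243 genes), 98.9% of 91 changes of 4-fold and 100% of 90 of 8-fold were called, with 11 false calls and 95.9% of intervals holding the true ratio. Clustering was run on 800 simulated cells from groups that differed 4-fold in 200 genes, and 97.9% belonged to the majority group of their cluster. A finer split would raise this share. Fewer variable genes, fewer components and a lower resolution were used than in the analysis.

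Alternatives planned before the data were examined were other cell filters, doublets kept, resolutions 0.5 and 2, 3000 variable genes, 20 components, list genes kept in clustering, scaling outside ribosomal, mitochondrial and immunoglobulin genes, thinning to 2000 UMIs and per-cell means. Chosen after seeing the data were the earlier naming rules, either RORγt DC-like cluster alone, male or female cells alone, clustering without sex-linked genes, and classes without cluster 9, cluster 19 or sub-cluster 5. Cells came from mice of both sexes by their sex-linked transcripts, so at least 2 animals contributed, but cells were not assigned to animals.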

Results

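Antigen-presenting cells of the RORγt reporter lineage were sampled from 2-week-old mice. The mice carried a RORγt-Cre transgene with a Cre-dependent tdTomato reporter, which labels cells that express Cre and their descendants. Live cells positive for tdTomato and for major histocompatibility complex (MHC) class II protein were sorted and profiled by droplet single-cell RNA sequencing with unique molecular identifiers (UMIs). The series held 3 libraries, and their barcode lists had 13482 entries for the lymph node library titled as mesenteric, 17975 for the library titled as other lymph nodes and 27642 for spleen. The counts of the first of these libraries were analysed here, and those of the other libraries were not analysed here. The titles and the tissue fields of both lymph node libraries disagree: the library titled as mesenteric has a tissue field naming pooled peripheral nodes, and the other carries the mesenteric field. The node of origin of the analysed cells is therefore left open. With 1 library there is no replicate, no p-values were computed for differences between cells, and the intervals of these comparisons are 95% intervals for counting error alone. The library had 135206367 UMIs in total and 500 to 164131 UMIs per barcode. After filtering and removal of called doublets, 12308 cells with a median of 9041 UMIs and 2890 genes were analysed.

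The first question was which cell types passed the gate. Most of the cells resembled group 3 innate lymphoid cells (ILC3s), lymphocytes that make the cytokine IL-22. The ILC3-like class had 7217 cells in 7 of the 22 clusters, or 58.6% of cells (exact binomial interval 57.8% to 59.5%). By sex-linked transcripts 98.9% of the assigned cells of cluster 8, which had 755 cells, were male, against 11.7% to 33.6% in the other ILC3-like clusters. T cell-like cells numbered 2339 (19.004%, 18.3% to 19.7%) and B cell-like cells 956 (7.77%, 7.30% to 8.25%). The class resembling natural killer cells or group 1 innate lymphoid cells had 464 cells (3.77%, 3.44% to 4.12%). Cells with the fixed markers of RORγt-positive dendritic cells (DCs) numbered 603 (4.90%, 4.52% to 5.30%), and mature DC-like cells numbered 155 (1.26%, 1.07% to 1.47%). No cluster was named as a conventional DC of type 1 or type 2, so the planned comparison of RORγt DC-like cells with such cells was not made. Clusters holding 574 cells (4.66%) stayed unnamed, among them a cluster of 199 cells led by cell cycle genes. Another was cluster 16, with 165 cells, which scored highest as macrophages and was led by Lyz2, Plbd1 and Il1b. The sort set these shares, and they also moved with the clustering: the ILC3-like share ranged from 40.3% to 58.6% over the alternatives and the mature DC-like share from 0.658% to 2.07%. Of cluster 2, an ILC3-like cluster led by Cacnb2, Prss2 and Eya1, 1321 cells were named as group 2 innate lymphoid cells at clustering resolution 0.5 and 1091 with 20 components.

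The RORγt DC-like class joined 2 clusters that differed widely. Cluster 12 had 381 cells, a median of 13975 UMIs and the leading genes Syt1, Dpp10 and Cadm2. Cluster 13 had 222 cells, a median of 21646 UMIs and the leading genes Prdm16, Asprv1, Dnase1l3, Col17a1 and Fabp1. The name of cluster 13 rests on a scoring rule chosen after the data were examined. It was left unnamed under 3 earlier versions of that rule, where the best-scoring class was epithelial cells once and type 2 conventional DCs in the others, and under the stricter cell filter, where it was mature DCs. At clustering resolution 2 its cells divided into an unnamed cluster of 121 cells, scored highest as type 2 conventional DCs, and a mature DC-like cluster of 100 cells. For some genes values are given for cluster 12 and cluster 13 beside those of the class.

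RNA of the MHC class II list, the genes that build and load the molecules used in the sort gate, was high in every named class except T cell-like and natural killer or ILC1-like cells. The 10 genes summed to 20276 counts per 1000000 UMIs (CPM) in RORγt DC-like cells (exact Poisson interval 20188 to 20364), 22571 in mature DC-like cells (22355 to 22790), 17363 in B cell-like cells (17263 to 17463) and 9928 in ILC3-like cells (9904 to 9952). The natural killer or ILC1-like class had 2141 CPM (2098 to 2185), and T cell-like cells had 197 (192 to 203). Unnamed cluster 16, the macrophage candidate, had 23477 CPM (23268 to 23688), above all named classes. The unnamed clusters 14, 15 and 21 had 1516, 124 and 352. The RORγt DC-like level was 2.04-fold that of ILC3-like cells, a log2 ratio of 1.03 (1.02 to 1.04). The ratio was 0.91 for cluster 12 alone and 1.16 for cluster 13 alone.

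**Figure D1:**
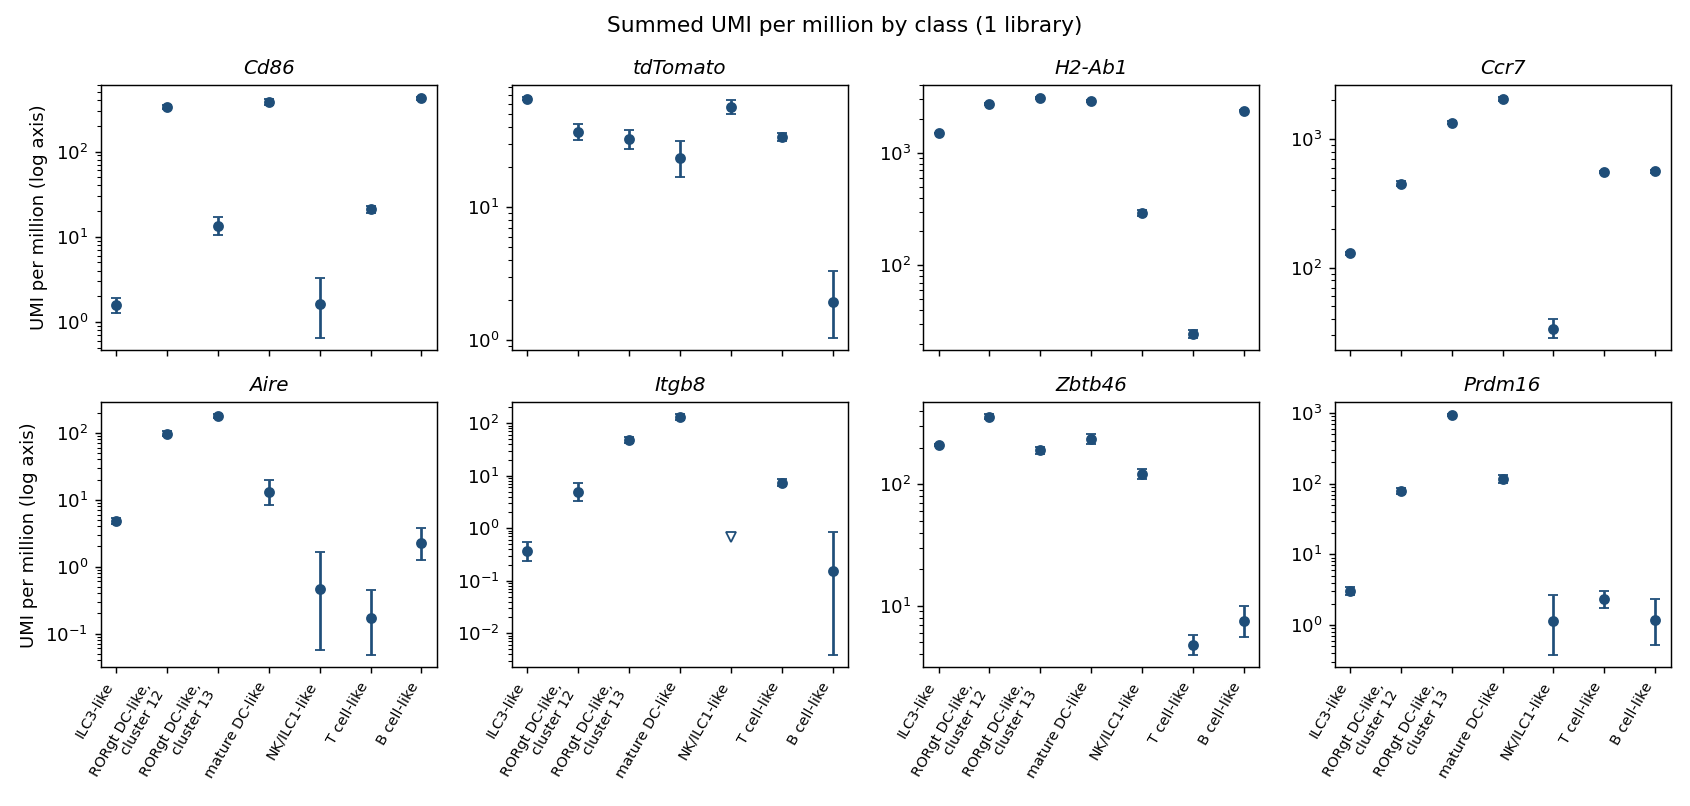
Summed CPM (log axis) of 8 genes in the named classes, with the RORγt DC-like class shown as cluster 12 and cluster 13. Points are the 1 library, bars are exact 95% Poisson intervals, and an open triangle marks a count of 0 at the limit of 3 counts. Aire was 176 CPM in cluster 13 and 96.3 in cluster 12, above the 4.81 of ILC3-like cells.

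The comparison of RORγt DC-like with ILC3-like cells asked how far cells of the same reporter lineage differ in antigen presentation genes. Of 150 list genes with at least 50 UMIs, 67 were at least 2-fold higher and 27 at least 2-fold lower with intervals excluding 0. With cluster 12 alone the counts were 56 and 34, and with cluster 13 alone they were 57 and 32.

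In the MHC class II list, 6 of 10 genes were at least 2-fold higher and 4 lay between. Ciita, the master regulator of MHC class II transcription, was 8.57-fold higher (log2 ratio 3.10, 2.99 to 3.21), with 3.21 in cluster 12 and 2.95 in cluster 13. H2-DMb2, part of a peptide-loading complex, was 4.27-fold higher. In the lysosomal processing list 7 of 11 genes were higher and 1 was lower. Its thiol reductase gene Ifi30 stood at 1036 against 20.8 CPM and its protease gene Ctsh at 468 against 5.62. In the MHC class I list 3 of 9 genes were higher and 6 lay between. Its regulator Nlrc5 had a log2 ratio of 3.10 (2.99 to 3.22) in the class, 0.38 in cluster 12 and 4.09 in cluster 13.

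Of 11 measured co-stimulatory and co-inhibitory ligand genes, 7 were higher and 3 lower. Cd86, a ligand of CD28, was 117-fold higher (log2 ratio 6.87, 6.59 to 7.17), and it stood at 333 CPM in cluster 12 and 13.5 in cluster 13. Cd40 was 17.1-fold higher. Pdcd1lg2, which encodes the PD-1 ligand PD-L2, was 11.7-fold lower, at 5.57 against 65.1 CPM. Itgb8, an integrin chain that takes part in activating TGF-β, was 67.2-fold higher (6.07, 5.47 to 6.72), with 4.999 CPM in cluster 12 and 48.7 in cluster 13. Furin and the integrin chain gene Itgav were 8.25-fold and 4.51-fold lower, and 2 of the 7 measured genes of the TGF-β list were higher and 3 lower. Aldh1a2, which makes retinoic acid, had a log2 ratio of 5.32 (4.75 to 5.94) at 17.4 CPM, with 4.41 in cluster 12 and 5.94 in cluster 13.

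Aire, the regulator of tissue antigen expression in the thymus, stood at 133 CPM in RORγt DC-like cells and 4.81 in ILC3-like cells (log2 ratio 4.79, 4.62 to 4.97). None of the thymic AIRE-dependent antigens on its list reached 50 UMIs. The homing receptor gene Ccr7 was 6.67-fold higher, at 450.5 CPM in cluster 12 and 1341 in cluster 13 against 129 in ILC3-like cells. Cxcr6 was 23.1-fold lower, with a log2 ratio of -4.53 in the class and -6.13 without sub-cluster 5. Over the homing list 1 of 10 genes was higher and 4 were lower. The chemokine gene Cxcl16 was 224-fold higher (7.81, 7.52 to 8.12). Ccl17 had a log2 ratio of 2.91 in the class, 3.78 in cluster 12 and -1.62 in cluster 13.

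In the list of type 3 and lymphotoxin cytokines, 7 of 8 genes were lower and none was higher. Il22, an effector cytokine of ILC3s, stood at 93.9 CPM against 2129 (log2 ratio -4.50, -4.60 to -4.41), with -3.84 in cluster 12, -6.13 in cluster 13 and -6.57 without sub-cluster 5, whose 80 cells held 750 of its UMIs. In B cell-like cells Il22 stood at 1.47% of its ILC3-like level, and no background was subtracted from these ratios. Csf2 was 31.2-fold lower on 4 UMIs. The list median of -3.39 lay below all 10000 random lists of like expression. The medians of the co-stimulatory ligand, myeloid cytokine and cell cycle lists lay above all of theirs, and the other 13 lists ranged from percentile 1.01 (TGF-β) to 99.99 (lysosomal). Among myeloid cytokines 6 of 10 genes were higher and 1 was lower, with Il1b 67.6-fold higher and Tnf 2.31-fold lower, at log2 ratios of -2.31 in cluster 12 and -0.51 in cluster 13. The transcription factor genes Spi1 and Spib, both used by myeloid cells and B cells, were 14.99-fold and 25.3-fold higher, and Tox was 5.80-fold lower. Zbtb46, often used as a DC marker, was 1.33-fold higher, at 281 against 211 CPM (0.41, 0.35 to 0.47), with 359 in cluster 12 and 191 in cluster 13. Among pattern recognition genes 4 of 6 were higher, with Clec7a 278-fold higher, and 1 was lower, Tlr4 at 10.7-fold on 2 UMIs. The interferon-stimulated gene Rsad2 was at 71.5 against 0.857 CPM, with a log2 ratio of 0.79 in cluster 12 and 7.48 in cluster 13.

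Of 14 cell cycle genes 11 were higher, with Mki67 at 52.2 against 3.83 CPM. The cluster of cycling cells that stayed unnamed lies outside the ILC3-like class, so this count sets a class that kept cycling cells against one that did not. Of 8 genes of the RANK and non-canonical NF-κB list 3 were higher, Relb 2.51-fold, and 1 of 12 immediate-early genes was higher and 3 were lower. The retinoid list had 3 of 6 genes higher and 1 lower, the chemokine list 4 of 8 higher, the transcription factor list 5 of 12 higher and 2 lower, and the interferon list 3 of 7 higher and 1 lower. Outside the lists and the genes used for clustering, the largest ratios were those of Gm15848, Gprc5c, Stra6l, Plppr4 and Ush1c. They had log2 ratios of 11.41, 10.77, 10.65, 9.80 and 8.98, each on 1 or 2 UMIs in ILC3-like cells. In cluster 12 the log2 ratios of these genes were 7.53, 4.62, 6.94, 5.21 and 4.94, and in cluster 13 they were 12.46, 11.87, 11.70, 10.91 and 10.04. Genes without a UMI in ILC3-like cells were set to 3 counts there, so they could be ranked below these genes. The lowest ratios were those of Gm52992, Gm20627, Snhg18, Gm33332 and A430088P11Rik, from -5.85 to -5.37, each on 1 or 2 UMIs in RORγt DC-like cells. Cluster 13 held no UMI of Gm20627 or Snhg18, so their values there, -2.86 and -2.79, are set by the limit of 3 counts. Genes without a UMI in RORγt DC-like cells could likewise be ranked less low than these.

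**Figure D2:**
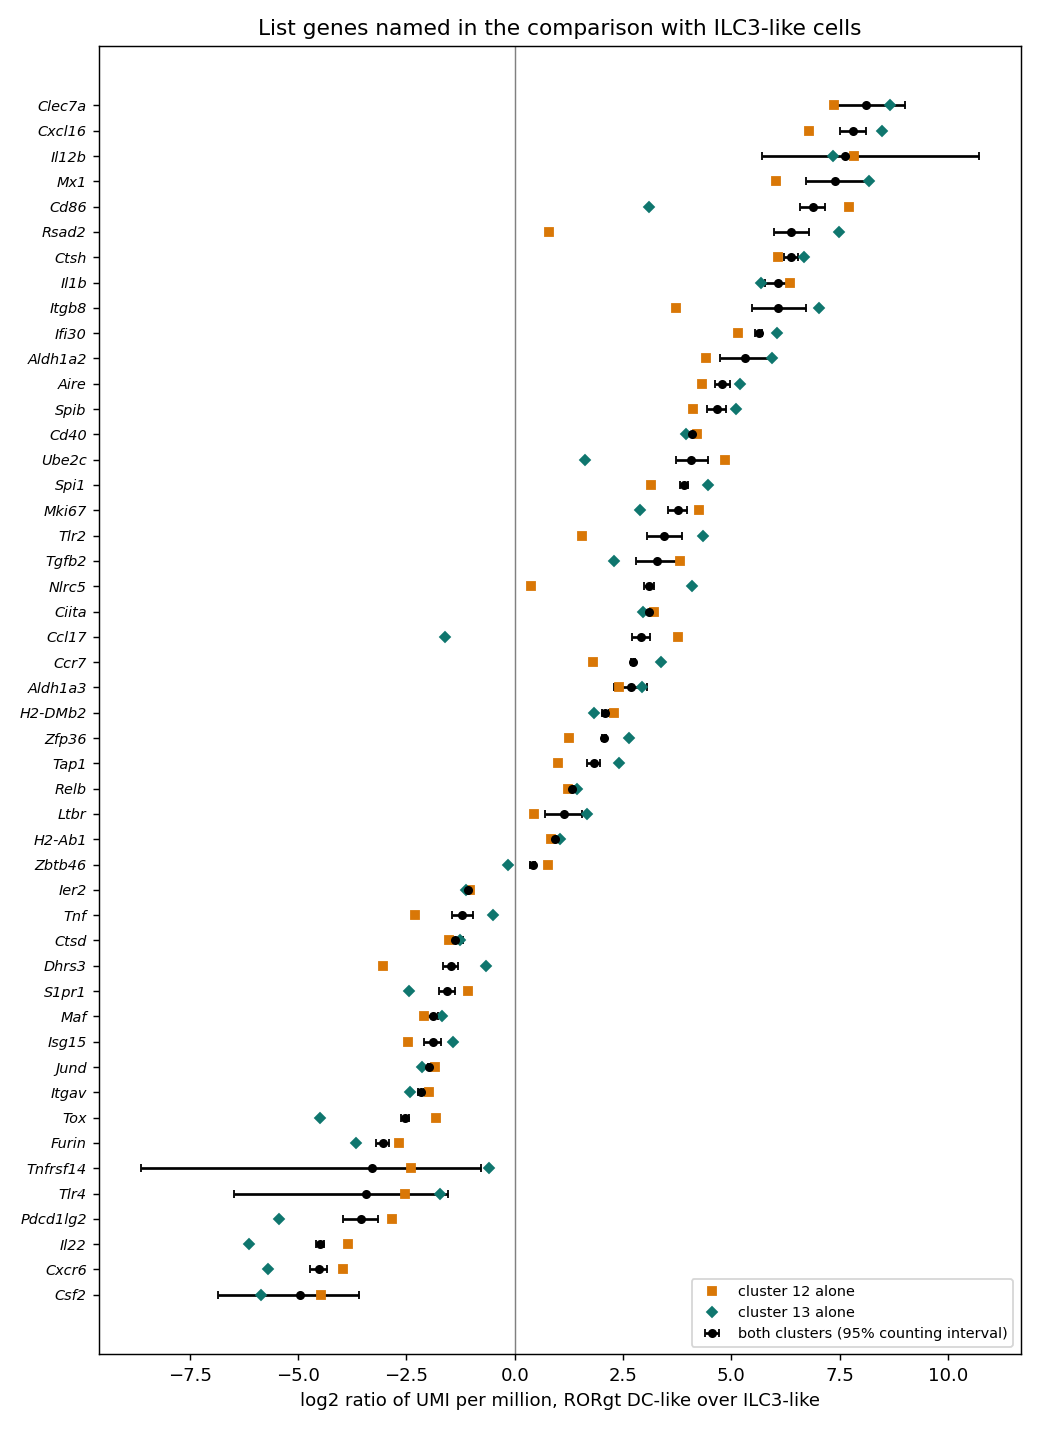
Log2 ratio of CPM in RORγt DC-like over ILC3-like cells for the named list genes. Black points are both clusters with exact conditional 95% intervals, orange squares cluster 12 alone and green diamonds cluster 13 alone. Il22 is low in both clusters, whereas Ccl17 lies on either side of 0 at 3.78 and -1.62.

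The comparison with mature DC-like cells, the migratory state of DCs, asked which genes set RORγt DC-like cells apart from other DCs in the library. Of 137 measured list genes, 39 were at least 2-fold higher and 38 at least 2-fold lower. With cluster 12 alone the counts were 41 and 47, and with cluster 13 alone they were 24 and 23. With cells thinned to 2000 UMIs, 24 genes were lower. Thinned cells and single clusters hold fewer UMIs, so fewer genes could reach a call, and smaller counts need not mean fewer differences. The mature DC-like class had 155 cells and 1839053 UMIs, and 74 of these cells were in cluster 19, with a median of 2680.5 UMIs. Over all 10649 measured genes the median log2 ratio was 0.52.

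Aire was 10.2-fold higher in the RORγt DC-like class (log2 ratio 3.35, 2.77 to 4.0007), with 2.88 in cluster 12 and 3.76 in cluster 13. At clustering resolution 2, where part of cluster 13 was named mature DC-like, the ratio of Aire was -1.17. Ltb, which encodes lymphotoxin β, was 4.92-fold higher. Tnfsf11, the RANK ligand gene, had a log2 ratio of 2.17 in the class, -0.23 in cluster 13 and 0.82 without sub-cluster 5. Tnfsf4, the OX40 ligand gene, stood at 75.8 CPM against 0.544, or 1 UMI, in mature DC-like cells (7.12, 4.64 to 12.43). Its ratio was -0.34 in cluster 13 and 5.97 without sub-cluster 5. Tnfsf4 was also a leading gene of ILC3-like cluster 2, at 63.2 CPM. Cxcl10 and Ccr6 were 7.01-fold and 7.22-fold higher, and the log2 ratio of Cxcl10 was 3.36 in cluster 12 and 1.70 in cluster 13.

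Lower genes included Ccl5, at 49.0 against 7017 CPM (-7.16, -7.29 to -7.03), and Il12b, at 5.96 against 195 (-5.03, -5.45 to -4.64). In male cells, with 22 of the mature DC-like class, the ratios of Ccl5 and Il12b were -8.29 and -8.45, and in female cells -6.08 and -4.53. Of the assigned cells of the class, 16.4% were male in cluster 18 and 66.7% in cluster 19, the cluster led by Ccl5. The split by sex therefore also changes the mix of these clusters, and their effects cannot be told apart here. Over the named genes set against mature DC-like cells, the median difference between the sexes was 0.60. Of the 55 named genes at least 2-fold apart, 52 had the same sign in both sexes. Nod1 and Hspa1a had opposite signs, and Ccl4 had no value in male cells. The largest difference was 5.82. Of 10 co-stimulatory and co-inhibitory ligand genes 7 were lower and 1 was higher, with Cd40 5.20-fold and Cd274 8.48-fold lower. In the MHC class I list 6 of 9 genes were lower, with the immunoproteasome genes Psmb8 and Psmb9 at -1.62 and -1.61 in the class and -0.93 for each in cluster 13. Itgb8 was 5.17-fold lower (-2.37, -2.63 to -2.11), at 25.2 against 130.5 CPM, with -4.71 in cluster 12 and -1.42 in cluster 13. Aldh1a2 was 11.7-fold lower, with log2 ratios of -4.46 in cluster 12 and -2.92 in cluster 13. Ccr7 was 2.39-fold lower, with -2.19 in cluster 12 and -0.62 in cluster 13. Among myeloid cytokines 5 of 8 genes were lower and 1 was higher, among chemokines 4 of 7 lower and 2 higher, and among lysosomal genes 3 of 11 lower and 1 higher. H2-Ab1 was level, at 2883 and 2887 CPM, while in the MHC class II list 3 of 10 genes were higher and none was lower. Of 13 cell cycle genes 11 were higher, in a class that kept the cycling cells of sub-cluster 4. Stmn1 was at 4.76 in cluster 12 and 1.59 in cluster 13. Mcm2 had 2 UMIs in mature DC-like cells, and its -0.33 with thinned cells is set by the limit of 3 counts. Against random lists, the medians of the co-stimulatory ligand and myeloid cytokine lists lay below all 10000 and that of the cell cycle list above all, and the other 14 ranged from percentile 0.05 (MHC class I) to 99.79 (type 3 cytokines). Zbtb46 had a log2 ratio of 0.25 in the class and -0.30 in cluster 13.

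Among other lists, the retinoid list had 4 of 6 genes between the calls and a median log2 ratio of 0.51. Type 3 and lymphotoxin cytokines had 3 of 5 genes higher and 2 lower, homing receptors 3 of 9 higher and 1 lower, and transcription factors 5 of 12 higher and 2 lower. Interferon-stimulated genes had 2 of 6 lower, with Isg15 13.1-fold lower. Pattern recognition genes had 2 of 5 higher and 2 lower, and immediate-early genes 3 of 12 higher and 2 lower. The TGF-β list 1 of 5 higher and 1 lower, and the RANK and NF-κB list 1 of 8 higher. Outside the lists and the genes used for clustering or naming, Cadm3, Slc14a1, Fat1, Fzd10os and Grb14 had the highest log2 ratios, 5.65 to 5.32. They had 1 to 3 UMIs in mature DC-like cells, and genes without a UMI there, set to 3 counts, could rank below them. Fzd10os, on 1 UMI in mature DC-like cells, was at -1.34 in cluster 13. With the same genes left out, Gm26535, Ifi209, Net1, Cacna1s and Abcg1 had the lowest log2 ratios, -5.07 to -3.58.

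Clustering within the RORγt DC-like class gave 5 sub-clusters of 218, 118, 104, 83 and 80 cells, given here by number. Sub-clusters 1, 4 and 5 came almost wholly from cluster 12, and sub-clusters 2 and 3 from cluster 13. The leading genes of sub-cluster 3 were Asprv1, Clu, Epsti1, Rsad2 and Ldb2, and Clu and Epsti1 were also leading genes of mature DC-like cluster 19. Of its 104 cells, 99 lay in the cluster named mature DC-like at clustering resolution 2, so its class is not settled. Aire was highest in sub-cluster 3 at 406 CPM (377 to 436), and it was 130.1 in sub-cluster 1 and 19.4 in sub-cluster 2. Ccr7 reached 2447 CPM in sub-cluster 3 and lay between 442 and 562 in the other sub-clusters. Itgb8 was 99.98 CPM in sub-cluster 3 (86.2 to 115) and at most 14.3 elsewhere. Cd86 was 535 CPM in sub-cluster 1, against 15.4 in sub-cluster 2 and 13.3 in sub-cluster 3. Sub-cluster 4 was led by the cycling genes Pclaf, H1f5, Stmn1 and Top2a. Sub-cluster 5 had Il22 at 561, Tnfsf11 at 451 and Cxcr6 at 118 CPM, genes that were high in ILC3-like cells.

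Sub-cluster 3 was set against sub-cluster 2 after these levels had been seen. Of 109 measured list genes 29 were at least 2-fold higher in sub-cluster 3 and 20 at least 2-fold lower. With cells thinned 5 were lower, on fewer UMIs and so with fewer genes open to a call. Aire was 20.9-fold higher (log2 ratio 4.39, 3.98 to 4.82) and Itgb8 7.003-fold higher (2.81, 2.30 to 3.34). In the MHC class I list 8 of 9 genes were higher, among them Nlrc5 at 12.95-fold, while none of 9 MHC class II genes was 2-fold higher or lower. Of 5 measured interferon-stimulated genes 3 were higher, with Rsad2 at 341 against 24.9 CPM. Icosl, Il15 and Cxcr5 were 4.65-fold, 5.74-fold and 12.8-fold higher. Ltb, Il1b and Il23a were 5.79-fold, 19.8-fold and 7.89-fold lower. Of 12 immediate-early genes, which can respond to tissue digestion, 5 were lower in sub-cluster 3, with Egr1 9.51-fold lower.

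**Figure D3:**
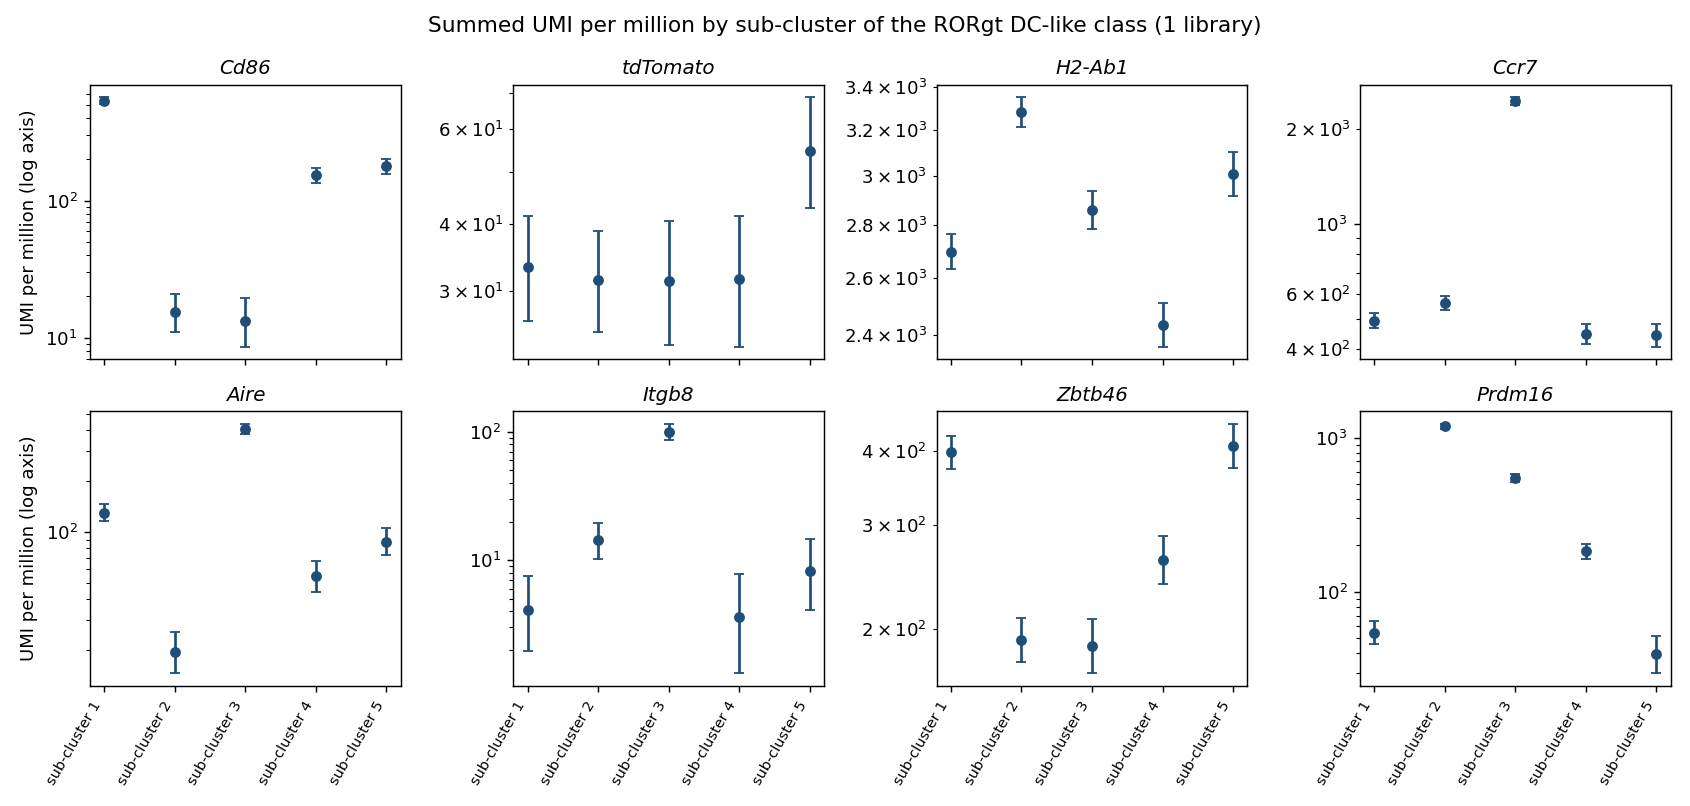
Summed CPM (log axis) of 8 genes in the 5 sub-clusters of the RORγt DC-like class. Points are the 1 library and bars are exact 95% Poisson intervals. Aire and Itgb8 peak in sub-cluster 3, at 406 and 99.98 CPM.

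In the GENCODE vM21 annotation of GRCm38, Aire lies on chromosome 10 from 78030022 to 78043610. Itgb8 lies on chromosome 12 from 119158022 to 119238802 and Ccr7 on chromosome 11 from 99144196 to 99155077. H2-Ab1 lies on chromosome 17 from 34257689 to 34269419 and Zbtb46 on chromosome 2 from 181387762 to 181459426. Counts are per gene and do not tell exons from introns or one isoform from another.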

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

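The earlier naming rules, single clusters, sexes, clustering without sex-linked genes and reduced classes were chosen after seeing the data; the other settings were planned. The cause of each change was not tested, apart from the cells that a setting leaves out by construction. Of 160 named gene ratios, 137 kept their sign in all alternatives that gave a value. Of 3273 values of these ratios under the alternatives, 33 had the other sign, 24 of them for ratios whose interval excluded 0, and 956 moved outside the counting interval without such a reversal. Values set by the limit of 3 counts are included. Of 219 values of the gene counts, the shares of 3 classes, the MHC class II ratio and the ratios of Aire and Itgb8 between sub-clusters, 49 moved. A match of sub-clusters was required to share at least 0.5 of the joint cells, a rule set after seeing values from poor matches. Sub-clusters 2 and 3 then had no match, and their contrast no value, under the stricter filter and at resolution 2, where cluster 13 was not named RORγt DC-like, nor under naming versions 1 to 3. Depth limited the description to list genes with at least 50 UMIs in both classes together.

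The MHC class II log2 ratio stayed above 0 in these alternatives. It was 0.89 under the stricter filter, 1.01 under the looser filter, 0.95 with doublets kept, 1.18 at resolution 0.5, 1.01 at resolution 2, 1.02 with 3000 variable genes, 1.19 with 20 components and 1.02 without sex-linked genes. It was 0.93 under naming versions 1, 2 and 3, 1.05 under version 4, 0.91 with cluster 12 alone, 1.16 with cluster 13 alone, 0.98 with the other scaling, 1.05 with thinned cells and 1.06 with per-cell means. It was 1.07 in male cells, 1.04 in female cells, 1.02 without cluster 9 and 1.04 without sub-cluster 5.

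The ILC3-like share was 55.7% under the stricter filter, 51.9% under the looser filter, 52.01% with doublets kept, 47.6% at resolution 0.5, 50.8% at resolution 2, 53.9% with 3000 variable genes, 40.3% with 20 components, 54.1% without sex-linked genes and 48.2% under naming versions 1 to 4. The RORγt DC-like share was 2.92% under the stricter filter, 3.19% at resolution 2, 3.10% under naming versions 1 to 3 and with cluster 12 alone, and 1.80% with cluster 13 alone. The mature DC-like share was 0.663% under the stricter filter, 1.48% under the looser filter, 0.658% at resolution 0.5 and 2.07% at resolution 2.

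Against mature DC-like cells, list genes at least 2-fold higher numbered 24 and lower 23 with cluster 13 alone, and lower 24 with thinned cells. Both settings hold fewer UMIs, so fewer genes could reach a call. Reversed log2 ratios in this comparison were Nod1 at -0.58 under the stricter filter, -0.98 with thinned cells and -0.52 in male cells, and Hspa1a at 3.57 in male cells. At resolution 2 they were Aire -1.17, Cxcr5 -1.87, Lta 0.66 and Maf -0.56. With cluster 13 alone they were H2-Ob -0.34, Tnfsf4 -0.34, Tnfsf11 -0.23, Zbtb46 -0.30 and Fzd10os -1.34. Tnfsf4 and Fzd10os had 1 UMI each in the mature DC-like class, so their signs rest on few UMIs. With thinned cells the reversed ratios were H2-Ob -0.20, Lta 0.61, Il10 -0.46, Myd88 0.12 and Mcm2 -0.33. In the mature DC-like class Mcm2 and Nod1 had 2 UMIs each before thinning, Il10 had 4 and H2-Ob 12. The thinned ratios of Mcm2 and Nod1 are set by the limit of 3 counts and show no lower level.

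Against ILC3-like cells, Ccl17 was -1.62 and Zbtb46 -0.15 with cluster 13 alone, and Tnfrsf14 was 1.60 with thinned cells. RORγt DC-like cells held 1 UMI of Tnfrsf14 before thinning, so its reversal rests on that UMI or on the limit of 3 counts. Between sub-clusters 3 and 2, thinned cells gave 5 lower list genes, on fewer UMIs, Aire 4.87, and the reversed Cxcl9 0.91, Tyms 0.17 and Hspa1b 0.75. Before thinning, sub-clusters 3 and 2 held 23 and 82 UMIs of Cxcl9, 13 and 40 of Tyms, and 24 and 91 of Hspa1b. The reversed signs of these genes therefore rest on few UMIs.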

Other observations

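The tests of free RNA and of depth in this part were chosen after their results had been seen, and those of droplets, gene span and correlation were set down before their results. The genes of the next sentences were also picked after their values were seen. The T cell-like class held several kinds of cells. In cluster 7 Cd8a stood at 247 counts per 1000000 UMIs (CPM), and in cluster 4 it was 0.826, where Cd4 was 237. Cluster 17, of 96 cells, had Foxp3 at 232 CPM and Ctla4 at 1241, the pair that marks regulatory T cells. Itgb8 was 148 CPM in that cluster, above its 48.7 in cluster 13. An unnamed cluster of 44 cells had Il1rl1 at 399.999 CPM, Gata3 at 397 and Il17a at 58.6, a mixture of group 2 innate lymphoid and γδ T cell genes. Among ILC3-like clusters Il22 ranged from 660 CPM in cluster 5 to 3153 in cluster 1. The reporter egfp had 0 UMIs over all barcodes.

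B cell-like cells held almost no reporter RNA, 1.95 CPM (1.04 to 3.34) against 65.6 in ILC3-like and 33.9 in T cell-like cells, although the gate selected tdTomato-positive cells. The tables argue against depth, since at 2000 UMIs per cell a tdTomato UMI was found in 0.109% of B cell-like and 10.96% of ILC3-like cells. They also argue against droplets holding a B cell and a reporter-positive cell for most of the 13 B cell-like cells with a tdTomato UMI, since 2 of these (15.4%, 1.92% to 45.4%) reached the 10th percentile of ILC3-like and T cell-like cells in the sum of 9 transcripts of those cells; for the 2 such droplets stay open. Free RNA may account for the few UMIs, since tdTomato stood at 2.98% of its ILC3-like level (1.58% to 5.09%) and Il22, Cxcr6, Il1r1, Kit and Tnfsf11 at 1.47% to 2.93% of theirs. Il7r stood lower, at 1.40% of its ILC3-like level, and Cd3e at 0.516% of its T cell-like level. The point value of tdTomato lay above those of all these transcripts. How these cells passed the gate was not tested, and no biological explanation was tested.

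T cell-like cells held little MHC class II RNA, although the gate selected cells with the protein. H2-Aa, H2-Ab1, H2-Eb1 and Cd74 stood at 1.46% to 1.69% of their ILC3-like levels. Droplets holding a T cell and a cell with MHC class II are argued against as the source of most of these UMIs, since the 5% of T cell-like cells with the most held 36.8% of them (28.4% to 44.7%); that is above the 16.8% of a spread by depth alone, so such droplets stay open for a part. Free RNA may supply these UMIs, and the highest of the 4 percents was 1.16 times the lowest. Droplets that also hold an ILC3-like cell would give near-equal percents too, so this value cannot tell such droplets from free RNA. Il22, at 0.923%, stood below all 4, which leaves sources other than ILC3-like cells open. Protein taken up from other cells would leave no RNA and stays open, as it was not tested, and no biological explanation was tested.

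ILC3-like cluster 9, with a median of 3057 UMIs against 9207 in the other ILC3-like clusters, had more Zbtb46 RNA (508 against 202 CPM) and less tdTomato RNA (19.7 against 67.0). Cells of another class of this library are argued against by the correlation over 169 list genes that are no markers, 0.957 with the other ILC3-like clusters and at most 0.790 with another named class, a difference of 0.167 (0.117 to 0.211). RNA of nuclei or leaky cells may explain the pattern, since genes at least 2-fold higher had a median span of 72.9 kb and genes at least 2-fold lower 8.74 kb, a ratio of 8.35 (7.73 to 9.32). Malat1, a nuclear RNA, was also higher, with a log2 ratio of 1.01, and mitochondrial UMIs made up a median of 5.40% against 2.05%. No biological explanation was tested.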
